A study of Homo sapiens with 6 samples.

How the data were processed

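The libraries were made from polyadenylated RNA of HepG2.2.15 cells with an Illumina TruSeq RNA kit, per the labels' protocols, and 3 libraries each came from cells kept for 3 days with saline or with YQSHJD. The values used are FPKM, fragments per kilobase of gene length scaled to library depth, as deposited by the authors in 1 table of 62709 genes with gene names, coordinates and lengths. The submitters' processing notes name CASAVA 2.19. The aligner, the counter, the strand setting, the genome build and the annotation are not given in the sources used here. Of the table's gene identifiers 58273 were also in GENCODE release 29 on GRCh38, and 70.4% of those had the same start and end there, 88.8% the same start or end. Coordinates are printed as the deposited table gives them. One line of the table was empty. The table also held 6 columns of values whose names match no sample of the series, and these were not used in any step.

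Multiplying FPKM by gene length gave whole multiples of 1 step per library for 100% of values, within a tolerance of 0.01 reads, so read numbers were recovered. The depth that the FPKM values imply was not the total of these reads but that total times a factor, 1.027, 1.028 and 1.049 in saline 1 to 3 and 0.885, 0.892 and 0.923 in YQSHJD 1 to 3. How the authors chose that factor is not given in the sources used here. With 13370372 to 15615649 reads per library, genes near 1 FPKM rest on few reads (35 to 49 for HSPB7 in the saline libraries), and changes of low genes are imprecise.

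Some genes that every cell uses had almost no reads. Of 137 members of 4 such lists (ribosomal proteins, proteasome subunits, oxidative phosphorylation and aminoacyl-tRNA synthetases), 9 did not pass the filter and 6 had at most 3 reads in every library, among them RPS9, VARS1 and PSMC4. A value of 0 in this table is therefore given only as listed at 0.

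The main test was fixed before the data were examined. Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept, which left 10966, and log2(FPKM + 1) was tested between the groups with limma 3.58.1 in R 4.3.3 (moderated statistics with trend and robust prior, two-sided), with Benjamini-Hochberg adjustment at 0.05. Fold changes on the log2 scale include the pseudocount of 1 and understate the change of low genes, and folds without log2 are ratios of mean FPKM. A total of 47 gene lists were also fixed before the data were examined, and the 43 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with all other genes, and fry does not.

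Genes were named by a rule fixed in advance. It took the 8 largest rises and the 8 largest falls among protein-coding genes that passed the test with no overlap between the groups. It added, for the 10 lists with the smallest camera p, the 3 members with the smallest p in the list's direction, and 15 genes fixed whatever their values, among them CYP1A1, CYP3A4, HMOX1, NQO1, ALB, AFP, HNF4A, CYP7A1, SLC10A1, DDIT3, CDKN1A, MKI67, IFIT1 and CXCL8. Genes of this rule that are left out are not reported here. Other genes are named as examples of their lists and were chosen after their values were seen.

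Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, TPM rescaling, limma without trend and robust prior, array weights, the replicate number as a block, a stricter adjusted p of 0.01, and leaving out each library. Chosen after seeing the data were limma-voom on the recovered reads and a GC correction, which removed from each library a loess trend (span 0.5) on the GC content of the longest GENCODE transcript, known for 98.6% of tested genes. Figures were drawn with matplotlib.

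The test was tried on simulated data in 10 simulations of 3 against 3 libraries, drawn from the saline means and the real depths with 200 genes changed. Genes were drawn independently, with a single dispersion taken from the saline libraries. For the YQSHJD comparison with about 11072 genes tested, it recovered 85.1% of genes changed 1.5-fold, 96.5% of those changed 2-fold and 98.4% of those changed 4-fold, and 9.4% of its calls were false. A raised list was called in 10 of 10 simulations and an unchanged list in 0. That result does not cover lists whose genes vary together, or libraries that stand apart from their group. With a simulated GC bias, a mean of 6780.8 unchanged genes were called, and 18.5 after GC correction. That bias was a linear trend shared by the treated libraries and steeper than the real one. These counts therefore do not show how many real calls come from GC bias, or how well the correction works on the real data.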

Results

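Polyadenylated RNA was sequenced from HepG2.2.15 cells, a human hepatoma line derived from HepG2 that carries the hepatitis B virus (HBV) genome and releases viral particles. The cells were kept for 3 days with a dilution of freeze-dried Yinqi Sanhuang Jiedu Decoction (YQSHJD), a traditional Chinese herbal medicine, which made up 10% of the medium, or with a saline control. The sample labels call the control physiological saline, whereas the treatment protocol in the same labels names PBS. Each group held 3 libraries, called saline 1 to 3 and YQSHJD 1 to 3 here. The reads in genes, recovered from the FPKM values and gene lengths, numbered 14829994, 14966790 and 15615649 in saline 1, 2 and 3. The YQSHJD libraries held 14579088, 13370372 and 15066527. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

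The series asks how YQSHJD changes gene expression in HepG2.2.15 cells. After 3 days with YQSHJD, targets of the aryl hydrocarbon receptor AHR and of NRF2, which respond to foreign compounds and to oxidants, rose as groups by camera (adjusted p = 0.108 for both lists with an estimated correlation) and held the 2 largest rises among protein-coding genes. CYP1A1, a cytochrome P450 that oxidises aromatic compounds, rose 42.5-fold, and AKR1B10, an aldo-keto reductase, rose 38.6-fold. HMOX1, the heme oxygenase that degrades heme, rose 15.6-fold. ID1, an inhibitor of helix-loop-helix transcription factors, fell 16.1-fold and DLK1, a membrane protein of fetal liver and hepatoma, fell 9.87-fold. By camera, genes of mitosis and DNA replication fell as groups (adjusted p = 0.284 and adjusted p = 0.108 with an estimated correlation). Proteasome subunits and the list of fatty acid oxidation and ketogenesis genes rose as groups by camera (adjusted p = 0.282 and adjusted p = 0.125 with an estimated correlation).

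Of 10966 genes tested with limma, 4536 differed between the groups at a Benjamini-Hochberg adjusted p under 0.05, and 2559 of them were higher and 1977 lower with YQSHJD. A fold of at least 2 on the log2(FPKM + 1) scale was reached by 274 higher and 287 lower genes. The values of the 2 groups did not overlap for 55.3% of the tested genes, where chance gives 10%. The authors' FPKM scaling put the median of all tested genes at a log2 difference of 0.04. Rescaling each library to a fixed sum, as TPM does, moved that median to -0.29 and the split to 876 higher and 4342 lower genes, and for groups whose balance of higher and lower members turned or became even under it both counts are given below. Without saline 1, 2805 genes passed, 1588 higher and 1217 lower. Without YQSHJD 1, the library that stood apart from the others, 4689 genes passed.

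CYP1A1 (ENSG00000140465, chromosome 15, positions 74719542 to 74725536) measured 9.52 ± 1.03 FPKM with saline and 404.4 ± 14.5 FPKM with YQSHJD (SD, n = 3 each), with 430 to 574 reads per library in saline. Its log2 difference was 5.27 with a standard error of 0.10 (limma adjusted p = 1.7e-08). AKR1B10 (ENSG00000198074, chromosome 7, 134527567 to 134541412) went from 5.05 ± 0.10 to 195.1 ± 5.44 FPKM, a log2 difference of 5.02 (adjusted p = 1.02e-08). It is a member of a family of near-identical genes, so its reads could be split between paralogs and its value is uncertain. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214) went from 14.2 ± 1.07 to 222.2 ± 30.9 FPKM, a log2 difference of 3.87 (adjusted p = 5.71e-07). The other large rises were those of HSPB7, a small heat shock protein, at 4.08, the glycerol and water channel AQP3 at 3.60 and the aldehyde dehydrogenase ALDH3A1 at 3.59. The leucine-rich repeat proteins LRRN4 and LRRC25 rose by log2 differences of 3.38 and 3.24. The adjusted p of these 5 genes lay between 7.82e-08 and 1.49e-06.

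ID1 (ENSG00000125968, chromosome 20, 31605283 to 31606515) fell from 413.3 ± 38.3 to 25.6 ± 5.40 FPKM, a log2 difference of -3.98 with a standard error of 0.15 (adjusted p = 1.58e-06). DLK1 (ENSG00000185559, chromosome 14, 100725705 to 100738224) fell from 159.7 ± 14.2 to 16.2 ± 4.08 FPKM, a log2 difference of -3.25 (adjusted p = 5.17e-06). CAPS, a calcium-binding protein, had a log2 difference of -3.04, COL9A2, a collagen chain, one of -2.61, and LOX, which cross-links collagen, one of -2.53. The ion channel HCN2 had a log2 difference of -2.36 and the semaphorin SEMA3B one of -2.36. CAPS overlaps RANBP3 and LOX overlaps SRFBP1, and no strand setting of the counting is given in the sources used here, so reads in these genes may be shared. Among the genes named below, CENPA overlaps SLC35F6, TNFAIP3 overlaps WAKMAR2, DDIT3 overlaps MARS1 and IFIT1 overlaps LIPA in the same way.

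**Figure D1:**
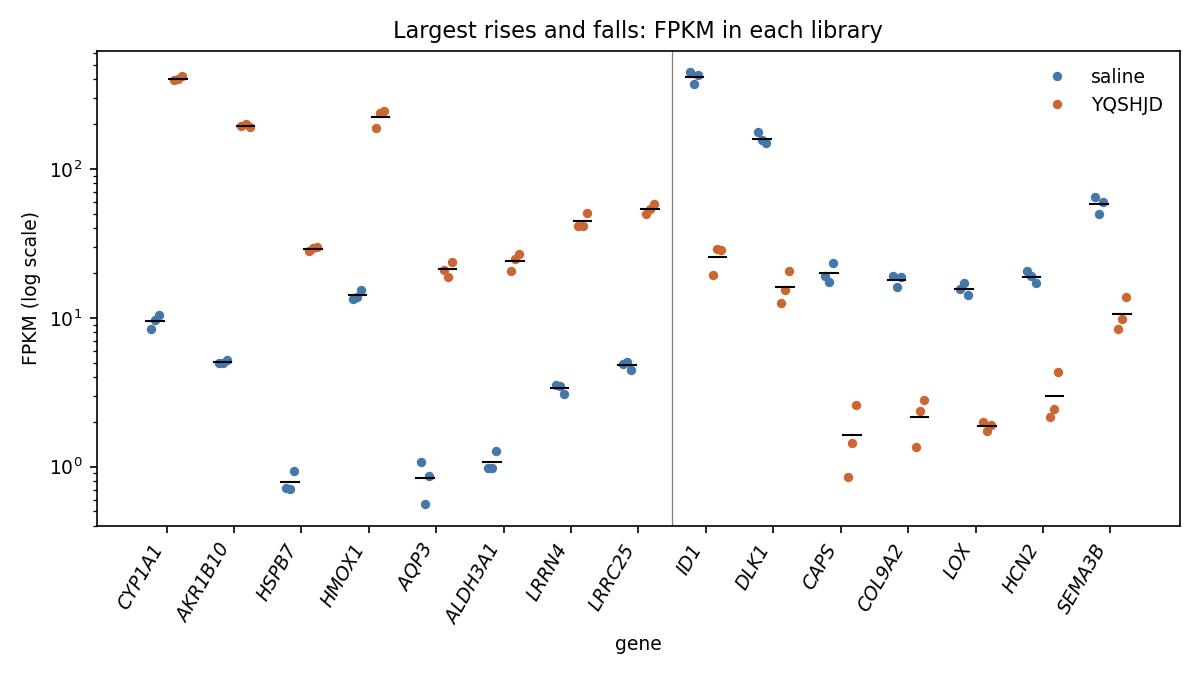
FPKM on a log scale in each of the 3 saline and 3 YQSHJD libraries (points) and the group mean (line) for the 8 protein-coding genes with the largest rise and 7 of the 8 with the largest fall. The groups did not overlap for any gene shown, and CYP1A1 went from a mean of 9.52 to 404.4 FPKM.

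Targets of NRF2, the transcription factor of the antioxidant response, rose together: 28 of 30 tested members were higher and 0 lower, with a median log2 difference of 1.47 (30 higher when adjusted over the list alone). NQO1, a quinone reductase, rose 5.54-fold from 361.0 ± 16.5 FPKM (log2 difference 2.47, adjusted p = 6.07e-07). GCLM, the regulatory subunit of glutathione synthesis, rose by a log2 difference of 2.60, the thioredoxin reductase TXNRD1 by 2.38 and the ferritin light chain FTL by 1.91. AKR1C1 and AKR1C2 had log2 differences of 2.06 and 2.11, which are uncertain because these paralogs are nearly identical. The members that did not pass were ABCC3 at 0.29 and SLC48A1 at 0.28. The list was higher than other genes by camera (adjusted p = 1.19e-18) but not with an estimated correlation (adjusted p = 0.108). After GC correction, and also without YQSHJD 1, 29 members were higher.

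Of 9 tested AHR targets, 8 were higher and 0 lower, over all genes and adjusted over the list alone, with a median of 1.37. Besides CYP1A1, NQO1 and ALDH3A1, they held CYP1A2 at 1.44 and the ADP-ribosyltransferase TIPARP at 0.75. NQO1 also stands in the NRF2 list, so the 2 lists are not independent. NFE2L2, which encodes NRF2 itself, had a log2 difference of 0.01. The list's adjusted p was 6.66e-06 by camera and the adjusted p was 0.108 with an estimated correlation. Targets of PXR and CAR, receptors that respond to drugs, held 9 higher and 1 lower of 11 members, also adjusted over the list alone, with a median of 1.09 (camera adjusted p = 0.000231, adjusted p = 0.125 with an estimated correlation). SULT2A1, a sulfotransferase, rose 6.20-fold from 16.2 ± 2.13 FPKM, and the transporter ABCB1 rose by a log2 difference of 1.14. UGT1A3 and UGT1A1, with log2 differences of 1.45 and 1.18, share exons in 1 locus, so their split is uncertain. CYP2B6, a classical CAR target, fell by 0.79. CYP3A4 was not tested, with 2 to 6 reads per saline library and 9 to 23 per YQSHJD library. Phase II conjugation enzymes held 10 higher and 1 lower of 14, also adjusted over the list alone, and 5 higher and 3 lower under TPM rescaling (median 0.47, camera adjusted p = 0.00485, adjusted p = 0.349 with an estimated correlation). MGST1, a microsomal glutathione transferase, rose by 2.82, and UGT2B4 fell by 1.13.

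Mitosis genes fell: 22 of 32 were lower and 0 higher, with a median of -0.60 (23 lower when adjusted over the list alone). The kinase AURKB fell 3.04-fold from 8.34 ± 0.99 FPKM, UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, fell 2.68-fold from 23.3 ± 0.58 FPKM, and CENPA, the centromeric histone, fell 2.81-fold from 9.27 ± 0.16 FPKM. MKI67, the proliferation marker, fell 2.12-fold (log2 difference -0.94, adjusted p = 0.000367). CCNB1 at -0.26 and AURKA at 0.05 were among the members that did not pass. The list's camera adjusted p was 1.06e-09, and the adjusted p was 0.284 with an estimated correlation. After GC correction 28 members were lower, and 27 without YQSHJD 1.

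DNA replication and G1/S genes fell as well, with 21 of 36 lower and 0 higher and a median of -0.41 (23 lower when adjusted over the list alone). MCM3, a subunit of the replicative helicase, fell 2.30-fold from 116.4 ± 5.34 FPKM, UHRF1, which maintains DNA methylation, fell 2.76-fold from 28.8 ± 3.00 FPKM, and the thymidine kinase TK1 fell 2.62-fold from 101.5 ± 3.16 FPKM. PCNA, the sliding clamp, had a log2 difference of -0.08. The camera adjusted p was 2.82e-08, and the adjusted p was 0.108 with an estimated correlation. After GC correction 27 members were lower, and 24 without YQSHJD 1. The replication-dependent histones held 3 higher and 0 lower of 6, with a median of 0.40 (4 higher when adjusted over the list alone). Their mRNAs lack a poly(A) tail, and the libraries were made from polyadenylated RNA. Only 6 of 20 listed members could be tested, so these values may not follow histone expression. H1-2 rose by 2.41, and the list's adjusted p was 0.0482 by camera, 0.0636 after GC correction, and the adjusted p was 0.324 with an estimated correlation. That call was lost without saline 2 (adjusted p = 0.0762), YQSHJD 2 (0.0773) or YQSHJD 3 (0.0705), with no filter (0.0646), with voom (0.0773) and without trend and robust in eBayes (0.0546).

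Proteasome subunits rose by small amounts, with 24 of 27 higher and 0 lower, also adjusted over the list alone, and a median of 0.49. PSMA5 rose 1.69-fold, PSMB2 1.59-fold and PSMD2 1.47-fold, from 15.5 ± 0.81, 42.4 ± 1.07 and 74.5 ± 1.69 FPKM. Under TPM rescaling 7 subunits were higher and 1 lower, and PSMD2 had a log2 difference of 0.20 (adjusted p = 0.127). After GC correction 25 subunits were higher, and 24 without YQSHJD 1. The list's adjusted p was 9.23e-07 by camera and the adjusted p was 0.282 with an estimated correlation. Heat shock genes held 13 higher and 2 lower of 18, also adjusted over the list alone, with a median of 0.42, and 8 higher and 2 lower under TPM rescaling (camera adjusted p = 0.00132, adjusted p = 0.125 with an estimated correlation). DNAJB4, a cochaperone, rose 4.91-fold from 2.10 ± 0.45 FPKM, the chaperone HSPA8 rose 1.79-fold from 225.9 ± 18 FPKM and the mitochondrial chaperonin HSPE1 rose 1.75-fold from 35.4 ± 0.66 FPKM. DNAJB4 overlaps GIPC2, and HSPE1 overlaps HSPD1. CRYAB and the collagen chaperone SERPINH1 fell by 0.54 and 0.77.

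Fatty acid oxidation and ketogenesis genes, targets of PPARA, rose: 16 of 22 were higher and 1 lower, also adjusted over the list alone, with a median of 0.77. CREB3L3, a liver transcription factor, rose 4.40-fold from 9.59 ± 0.74 FPKM, and the lipid droplet protein PLIN2 rose 4.01-fold from 39.2 ± 2.32 FPKM. CPT1A, the rate-limiting step of fatty acid entry into mitochondria, rose 2.39-fold from 16.6 ± 0.32 FPKM. ECI1, an isomerase of the same pathway, fell by 0.78. After GC correction, and also without YQSHJD 1, 17 members were higher. The camera adjusted p was 2.4e-06, and the adjusted p was 0.125 with an estimated correlation. Gluconeogenesis and glycogen genes held 6 higher and 0 lower of 8, also adjusted over the list alone, with a median of 0.45, and 3 higher and 2 lower under TPM rescaling. The pyruvate carboxylase PC rose by 1.37 (camera adjusted p = 0.0327, 0.0507 after GC correction, and adjusted p = 0.282 with an estimated correlation). Nuclear genes of oxidative phosphorylation held 24 higher and 0 lower of 39, also adjusted over the list alone, with a median of 0.35, and 5 higher and 2 lower under TPM rescaling. UQCRH of complex III rose 1.63-fold, ATP5F1A of the ATP synthase 1.67-fold and NDUFA4 1.53-fold; the call of NDUFA4 was lost under TPM rescaling (log2 difference 0.25, adjusted p = 0.0583). Without YQSHJD 1, 25 members were higher. The list's camera adjusted p was 1.92e-05, and the adjusted p was 0.349 with an estimated correlation.

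Targets of NF-kappaB fell: 8 of 12 were lower and 1 higher, with a median of -0.45 (9 lower and 1 higher when adjusted over the list alone). ICAM1, an adhesion molecule, fell 2.48-fold from 47.3 ± 5.82 FPKM. NFKBIA and TNFAIP3, feedback inhibitors of NF-kappaB, fell 1.69-fold and 1.63-fold, from 57.4 ± 2.95 and 5.71 ± 0.21 FPKM. TNFAIP2 rose by 0.87. CXCL8, the chemokine interleukin-8, had a log2 difference of -0.34 (adjusted p = 0.0721), -0.47 without YQSHJD 1 (adjusted p = 0.00672), -0.73 under TPM rescaling (adjusted p = 0.00571), -0.46 with array weights (adjusted p = 0.000202) and -0.63 after GC correction (adjusted p = 0.00103). The list's adjusted p was 0.00307 by camera, and the adjusted p was 0.236 with an estimated correlation. TGF-beta and matrix genes held 10 lower and 2 higher of 20, with a median of -0.33 (11 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.00824, adjusted p = 0.349 with an estimated correlation). ID1 and the matrix protein SPARC, at -2.35, were the members with the largest falls, and THBS1, a matrix glycoprotein, rose by 0.48.

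**Figure D2:**
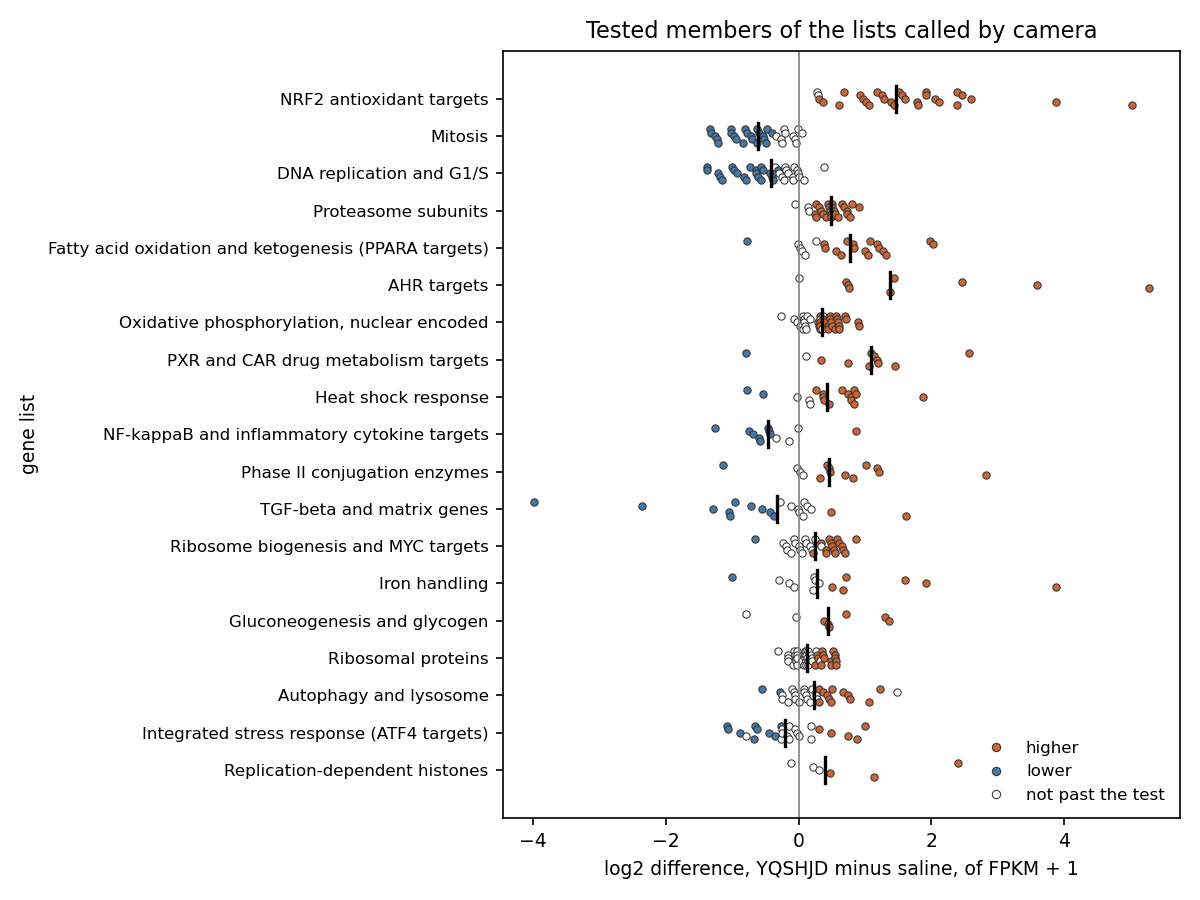
Log2 difference of FPKM + 1 between YQSHJD and saline for each tested member (points) of the 19 lists called by camera with a preset correlation, with each list's median (line). Filled points passed the limma test; the NRF2 targets have a median of 1.47 and the mitosis genes one of -0.60, and the medians of the ribosome biogenesis, ribosomal protein, iron and autophagy lists fell below 0 under TPM rescaling.

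In all, camera called 19 of the 43 lists with enough tested members, 14 higher and 5 lower. With an estimated correlation it called 0, with 7 lists at an unadjusted p under 0.05, and fry, which asks only whether a list's own genes move one way, called 28. The estimate lay above the preset 0.01 for some lists, such as mitosis (0.28) and NRF2 (0.105). It lay under 0.01 for others, such as AHR (0.006), heat shock (0.001) and PXR and CAR (-0.031). The unadjusted camera p of these others rose too, for AHR from 9.29e-07 to 0.00755, so a higher correlation was not the reason there. Camera called 16 lists after GC correction and 19 without YQSHJD 1, at the preset correlation. With no filter on low values it called 23 of 47, among them interferon-stimulated (adjusted p = 0.0303), hepatocyte secreted (0.0481), bile acid (0.03) and cholesterol synthesis genes (0.0449), which the main test did not call, and with a filter at FPKM 5 it called amino acid catabolism genes higher (0.0398). Ribosome biogenesis and MYC targets held 15 higher and 1 lower of 31, also adjusted over the list alone, and 1 higher and 6 lower under TPM rescaling (camera adjusted p = 0.026, adjusted p = 0.349 with an estimated correlation). NPM1 rose by 0.86, while MYC itself stood at -0.05. Ribosomal protein genes held 14 higher and 0 lower of 45 (13 higher when adjusted over the list alone) with a median of 0.13, against 0 higher and 11 lower under TPM rescaling (camera adjusted p = 0.0432, adjusted p = 0.775 with an estimated correlation). Autophagy and lysosome genes held 13 higher and 2 lower of 32, also adjusted over the list alone, and 5 higher and 9 lower under TPM rescaling (camera adjusted p = 0.0432, adjusted p = 0.284 with an estimated correlation). GLA, a lysosomal galactosidase, rose by 1.23. Iron handling genes held 6 higher and 1 lower of 14, also adjusted over the list alone, and 4 higher and 4 lower under TPM rescaling; FTH1, FTL and HMOX1, which also stand in the NRF2 list, led the rise (camera adjusted p = 0.0327, 0.067 after GC correction, and adjusted p = 0.307 with an estimated correlation). Targets of ATF4 in the integrated stress response held 9 lower and 5 higher of 26 (10 lower and 5 higher when adjusted over the list alone). The serine pathway enzymes SHMT2 and PHGDH fell by 1.07 and 0.88, and ATF3 and PPP1R15A rose by 1.00 and 0.88. That list's adjusted p was 0.0482 by camera, 0.0534 after GC correction, and the adjusted p was 0.499 with an estimated correlation. DDIT3 had a log2 difference of 0.18 (adjusted p = 0.187), -0.16 under TPM rescaling (adjusted p = 0.266) and 0.29 with array weights (adjusted p = 0.00192). The calls of 4 of these lists were lost under TPM rescaling and also without single libraries. Under TPM rescaling the camera adjusted p was 0.0704 for ribosome biogenesis, 0.939 for ribosomal proteins, 0.153 for autophagy and 0.0958 for the ATF4 list, which then held 2 higher and 18 lower. The ribosomal protein call was also lost under quantile normalization (8 higher and 3 lower, adjusted p = 0.856) and median-of-ratios scaling (adjusted p = 0.0784). With array weights the ATF4, autophagy and iron calls were lost (adjusted p = 0.114, 0.0622 and 0.0537), and with a filter at FPKM 5 those of ribosomal proteins and autophagy (adjusted p = 0.076 and 0.0729). Without trend and robust in eBayes the ATF4 and ribosomal protein calls were lost (adjusted p = 0.0554 for both), and so they were with a replicate block (0.0708 and 0.0568). The ATF4 list did not pass without any 1 library other than YQSHJD 2 (adjusted p from 0.0533 to 0.0765), and ribosome biogenesis did not pass without YQSHJD 3 (0.0665). Ribosomal proteins did not pass without saline 1 (0.0604), saline 2 (0.117) or YQSHJD 2 (0.245), nor did the autophagy list without saline 3 (0.0945), YQSHJD 2 (0.0528) or YQSHJD 3 (0.0557).

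Liver identity genes moved both ways. Albumin ALB rose 2.26-fold from 940.2 ± 96.0 FPKM (adjusted p = 0.000499) and alpha-fetoprotein AFP 1.90-fold from 170.3 ± 18.8 FPKM (adjusted p = 0.00121). Of 21 hepatocyte secreted and lipoprotein genes 9 were higher and 4 lower (11 and 5 when adjusted over the list alone; camera adjusted p = 0.234), against 7 higher and 8 lower under quantile normalization and 6 higher and 8 lower under TPM rescaling. APOA4 rose by 1.87 and AHSG fell by 0.85. Among 15 oncofetal hepatoma genes 5 were higher and 2 lower, also adjusted over the list alone, against 2 higher and 6 lower under TPM rescaling and 5 higher and 6 lower after GC correction, and the median of -0.02 and the mean of 0.15 differed in sign (camera adjusted p = 0.885). Liver transcription factors that act on HBV promoters held 6 higher and 7 lower of 22 (8 and 9 when adjusted over the list alone; camera adjusted p = 0.476), against 6 higher and 10 lower under quantile normalization and 2 higher and 11 lower under TPM rescaling. FOXA3 and CEBPA fell by 1.47 and 1.33, while PPARA and NR5A2 rose by 0.85 and 0.86. HNF4A, the central hepatocyte regulator, rose 1.44-fold, and stood at a log2 difference of 0.16 under TPM rescaling (adjusted p = 0.372). Host factors of HBV entry and cccDNA held 3 higher and 5 lower of 20, also adjusted over the list alone (camera adjusted p = 0.476), against 1 higher and 13 lower under TPM rescaling and 4 higher and 9 lower after GC correction. SLC10A1, the HBV entry receptor, had 0 to 3 reads per library, and CYP7A1, the rate-limiting enzyme of bile acid synthesis, was listed at 0 in all 6 libraries. Viral transcripts were not analysed here.

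Acute phase proteins held 5 higher and 5 lower of 15, also adjusted over the list alone, and 1 higher and 7 lower under TPM rescaling (camera adjusted p = 0.768), with FGB at 1.17 and SERPINA3 at -0.72. Complement and coagulation genes held 4 higher and 5 lower of 19 (5 and 5 when adjusted over the list alone), against 2 higher and 8 lower under TPM rescaling, and the median of 0.06 and the downward test differed in sign (camera adjusted p = 0.885). C3 fell by 1.29 and F11 rose by 1.76. Bile acid genes held 4 higher and 2 lower of 12, also adjusted over the list alone, and 3 higher and 4 lower under TPM rescaling (camera adjusted p = 0.476). Amino acid catabolism and urea cycle genes held 7 higher and 2 lower of 18 (7 and 5 when adjusted over the list alone), and 5 higher and 8 lower under TPM rescaling. The median of -0.03 and the mean of 0.27 differed in sign (camera adjusted p = 0.36). HGD and FAH, enzymes of tyrosine breakdown, rose by 1.05 and 1.13.

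Cholesterol synthesis genes held 10 higher and 2 lower of 23 (11 and 2 when adjusted over the list alone; camera adjusted p = 0.21), and 2 higher and 6 lower under TPM rescaling. MSMO1, a sterol oxidase of the pathway, rose by a log2 difference of 1.00, and the regulator SREBF2 fell by 0.54. Fatty acid and triglyceride synthesis genes held 5 higher and 1 lower of 20, also adjusted over the list alone (camera adjusted p = 0.811), and 1 higher and 8 lower under TPM rescaling. The 1 lower gene of the main test was their regulator SREBF1 at -1.16. Glycolysis genes held 10 higher and 4 lower of 19, also adjusted over the list alone (camera adjusted p = 0.0801, with 0.00773 after GC correction, 0.0301 without YQSHJD 1 and 0.00128 with no filter), and 2 higher and 4 lower under TPM rescaling. Hypoxia genes held 8 higher and 7 lower of 21 (9 and 7 when adjusted over the list alone; camera adjusted p = 0.875), against 5 higher and 9 lower under TPM rescaling and 6 higher and 8 lower after GC correction. Neutral amino acid and solute transporters held 8 higher and 6 lower of 17, also adjusted over the list alone (camera adjusted p = 0.811), against 5 higher and 6 lower under median-of-ratios scaling and quantile normalization, 2 higher and 9 lower under TPM rescaling and 5 higher and 7 lower after GC correction.

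Interferon-stimulated genes held 8 higher and 3 lower of 17 (8 and 5 when adjusted over the list alone; camera adjusted p = 0.311), and 2 higher and 5 lower under TPM rescaling. ISG15 rose by 0.58, OAS1 by 0.82 and PARP14 by 0.89, and IFI35 fell by 0.78. IFIT1 was not tested, at 1 to 26 reads per library. Genes of innate nucleic acid sensing held 5 higher and 2 lower of 11, also adjusted over the list alone (camera adjusted p = 0.796), and 1 higher and 4 lower under TPM rescaling. The 6 tested antigen presentation genes held 2 higher and 1 lower, also adjusted over the list alone, against 1 higher and 3 lower under TPM rescaling, and their median of -0.10 and mean of 0.10 differed in sign (camera adjusted p = 0.946).

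Targets of p53 held 8 higher and 5 lower of 25 (10 and 5 when adjusted over the list alone; camera adjusted p = 0.664), and 1 higher and 9 lower under TPM rescaling. CDKN1A, the inhibitor p21, rose 1.34-fold from 173.3 ± 7.91 FPKM (adjusted p = 0.00619), and stood at a log2 difference of 0.06 under TPM rescaling (adjusted p = 0.713). Apoptosis regulators held 5 higher and 6 lower of 29 (5 and 5 when adjusted over the list alone; camera adjusted p = 0.885), against 3 and 12 under TPM rescaling. Genes of the unfolded protein response held 7 higher and 3 lower of 24 (7 and 4 when adjusted over the list alone; camera adjusted p = 0.776), against 4 and 4 under median-of-ratios scaling, 4 and 5 under quantile normalization, 0 and 10 under TPM rescaling and 3 and 5 after GC correction. Aminoacyl-tRNA synthetases held 6 higher and 4 lower of 17 (7 and 5 when adjusted over the list alone; camera adjusted p = 0.796), against 4 and 5 under median-of-ratios scaling and quantile normalization, 2 and 7 under TPM rescaling and 3 and 3 after GC correction. Metallothioneins and zinc genes held 1 higher and 2 lower of 5, also adjusted over the list alone, and the median of 0.15 and mean of -0.17 differed in sign (camera adjusted p = 0.688). Wnt targets held 4 higher and 7 lower of 19 (4 and 9 when adjusted over the list alone; camera adjusted p = 0.311), with NOTUM at -1.82, against 3 and 12 under TPM rescaling. Immediate early and MAPK feedback genes held 8 higher and 11 lower of 28 (8 and 14 when adjusted over the list alone; camera adjusted p = 0.111), against 3 and 17 under TPM rescaling.

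Markers of other cell types were tested in small numbers. Of 2 fibroblast and stellate cell markers FBLN1 was lower, at -0.73 (2 lower when adjusted over the list alone). Of 3 leukocyte markers CD4 and CD3D were lower, at -1.33 and -0.72, and LYZ was higher at 1.23. Of 4 endothelial markers 3 were higher, PECAM1, ESAM and LYVE1, at 0.51, 0.82 and 0.72. Of 2 markers of keratinocyte or kidney lines SFN was higher, at 1.71. The counts of these last 3 lists were the same when adjusted over the list alone.

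The 2 mitochondrial rRNAs, chosen after their values were seen, rose as well. MT-RNR2, the 16S rRNA, made up 1.67% to 1.70% of reads in the saline libraries and 4.35% to 5.46% in the YQSHJD libraries, a log2 difference of 1.77 in FPKM (adjusted p = 1.69e-05). MT-RNR1, the 12S rRNA, made up 0.25% to 0.26% and 1.25% to 1.55%, a log2 difference of 2.67 (adjusted p = 1.58e-06). The 13 mitochondrial mRNAs held 5 higher and 1 lower, also adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.284). Under quantile normalization 0 were higher and 7 lower, with a median of -0.30, and camera with a preset correlation called the list lower (adjusted p = 0.00107), and under TPM rescaling 2 were higher and 5 lower. MT-ND1 and MT-ND2, which follow the rRNAs on the chromosome, rose by 1.25 and 0.98, while MT-CO1 stood at 0.05 (adjusted p = 0.731).

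**Figure D3:**
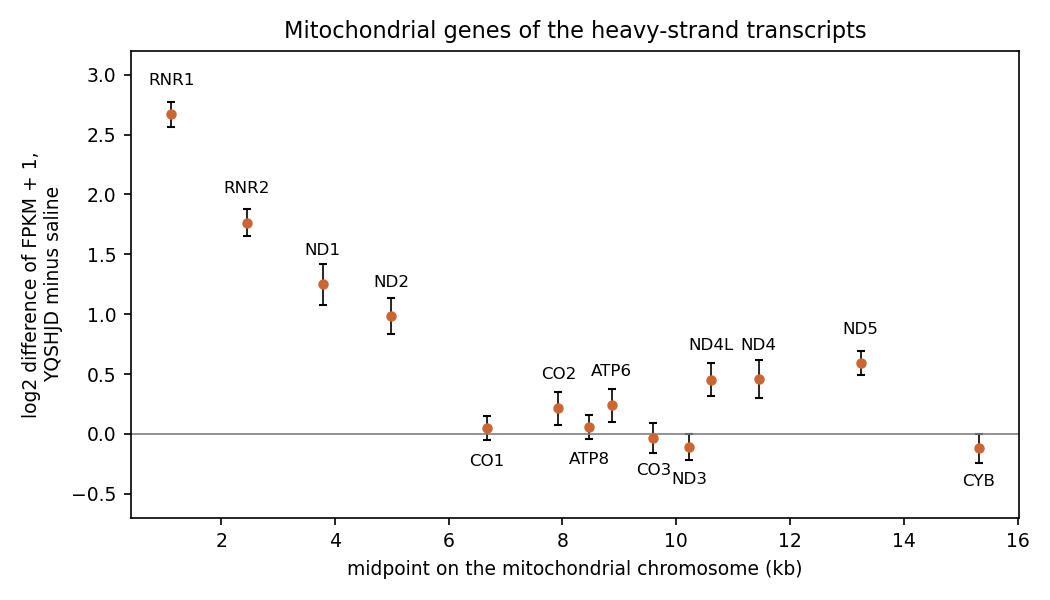
Log2 difference of FPKM + 1 between YQSHJD and saline with its standard error for 14 mitochondrial genes of the heavy-strand transcripts, by midpoint on the chromosome in kb (3 libraries per group). MT-RNR1 stands at 2.67, MT-RNR2 at 1.77, MT-ND1 at 1.25 and MT-CO1 at 0.05.

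The libraries also differed in ways that the treatment labels do not cover. Across genes, which are not independent replicates, the log2 difference between the groups correlated with transcript GC content at a Spearman rho of -0.453. YQSHJD 1 had the strongest trend of the 6 libraries, from a median of 0.30 above the mean of all libraries in the lowest decile of GC content to -0.44 in the highest. The trend was weaker in YQSHJD 2, from 0.10 to -0.09, and YQSHJD 3 went slightly the other way, from 0.01 to 0.06. Its recovered reads differed from those of YQSHJD 2 and YQSHJD 3 by a chi-square per degree of freedom of 20.98 and 39.3, against 8.47 between those 2 libraries and 6.62 to 10.2 between saline libraries. No pair of replicates agreed within sampling noise, which does not show whether they were separate cultures. The first principal component held 73.1% of the variance and separated the groups. Genes with at least 1 read numbered 20476 to 21065 in saline and 18543 to 20068 with YQSHJD. After GC correction 4843 genes passed, 3502 of them shared with the main result, all with the same direction.

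**Figure D4:**
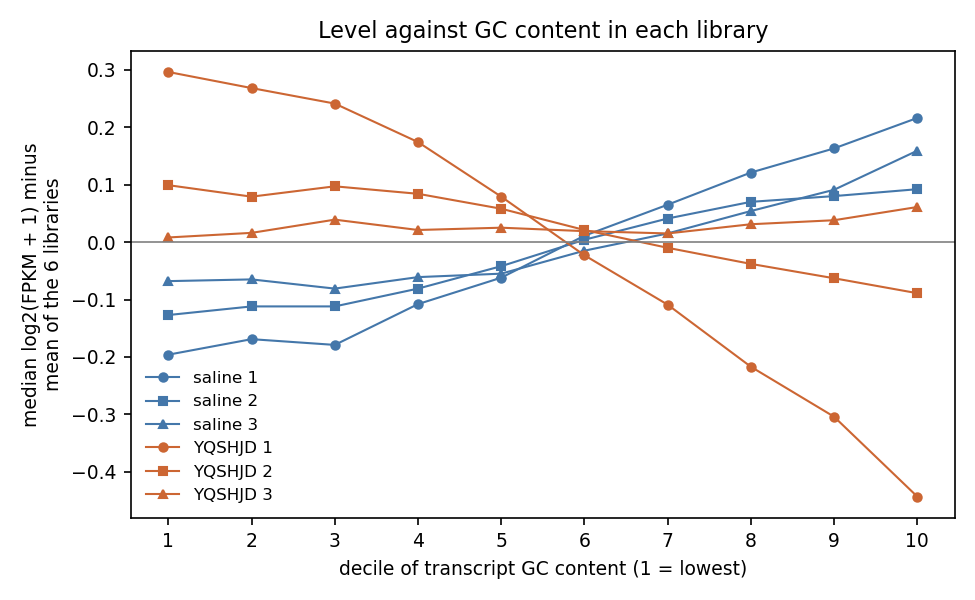
Median of log2(FPKM + 1) minus the mean of the 6 libraries, in deciles of transcript GC content, for each library (lines). YQSHJD 1 runs from 0.30 in the lowest decile to -0.44 in the highest, YQSHJD 2 from 0.10 to -0.09 and YQSHJD 3 from 0.01 to 0.06. Saline 1 runs from -0.20 to 0.22, saline 2 from -0.13 to 0.09 and saline 3 from -0.07 to 0.16.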

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

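The GC correction and the voom test were chosen after seeing the data; the others were fixed before. Of 56 tested genes taken by the rule or weighed below, 49 kept their direction and their side of the threshold under every alternative in which they were tested, and of the 19 lists 12 did so under every alternative with a preset correlation. With an estimated correlation camera called 0 lists, and at the preset one with no filter 23, with glycolysis, interferon-stimulated, hepatocyte secreted, bile acid and cholesterol synthesis genes among the gained ones. The count of 4536 genes became 2957 with no filter (1606 higher), where 26577 genes were tested, 7378 with array weights (4142 higher, 3236 lower), whose estimation did not fully converge, 2482 at an adjusted p under 0.01 and 561 with a fold of at least 2. That last count became 894 and 957 with pseudocounts of 0.1 and 0.01, 966 with voom and 1086 with TPM rescaling. A smaller pseudocount shrinks log2 differences less. TPM rescaling divides each library by its FPKM sum, which averaged 351080 with saline and 451666 with YQSHJD, so it lowered the YQSHJD values. Within that sum the mean FPKM of MT-RNR1 rose from 2574 to 16470 and that of MT-RNR2 from 10440 to 35730. For the other changes the cause was not tested. TPM rescaling gave 876 higher and 4342 lower genes and turned DDIT3 to -0.159 (adjusted p = 0.266), while array weights called it higher at 0.286 (adjusted p = 0.00192), and median-of-ratios scaling gave 2176 higher and 2292 lower. Leaving out 1 library gave 2805 to 4812 genes (1588 to 2675 higher, 1217 to 2188 lower), 474 to 660 with a fold of at least 2, and 15 to 19 lists; the lowest total was without saline 1. No sign of pairing by replicate number was seen: deviations of same-numbered libraries correlated at -0.245, -0.112 and -0.040, and no library correlated best with its own number. Deviations from a mean of 3 libraries are tied to each other, so these correlations cannot show that no day or culture was shared. With the replicate number as a block 3707 genes and 17 lists were called. Low read numbers limit what these depths can show for genes under 1 FPKM.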

Other observations

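The test of GC trends within groups and the tests of poly(A) selection, of all mitochondrial RNA, of the heavy-strand gradient and of the second BMP-SMAD list without JUNB were chosen only after the result was seen, and so was the GC correction. The genes of the next paragraph, the mitochondrial rRNAs and the 6 genes ID1, SMAD6, SMAD7, SMAD9, BAMBI and ATOH8 were picked after their values were seen.

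Single genes, not tested as a group, moved in both directions with YQSHJD. IL11, a cytokine of the interleukin-6 family, rose from 1.33 ± 0.09 to 11.7 ± 0.90 FPKM (SD, n = 3 each; log2 difference 2.45, limma adjusted p = 1.58e-06), and the decoy receptor IL1R2 rose by 2.46. The growth factor ligands AREG and EREG rose by 2.10 and 1.37, the phosphoprotein SPP1 by 2.15, WNT11 by 2.68 and the insulin-like growth factor binding protein IGFBP1 by 2.65. MMP3, a matrix metalloproteinase, was listed at 0 in the saline libraries and at 3.92 ± 1.13 FPKM with YQSHJD. CIDEC, a lipid droplet protein, rose by 2.54, the water channel AQP8 by 2.81 and MAT1A, the liver enzyme of S-adenosylmethionine synthesis, by 2.14. Falls were seen for the collagen chain COL9A3 at -2.33, the proteoglycan BGN at -1.99, the transglutaminase TGM2 at -1.97, CHI3L1 at -2.00, the growth factor PDGFA at -1.85 and the receptor NGFR at -2.20. In the list of immediate early and MAPK feedback genes the falls held SPRY4 at -1.41, EGR1 at -1.39, ETV5 at -1.19 and ETV4 at -1.15, and the rises held FOSL1 at 0.92.

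Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real grouping, the real one itself. The other splits called at most 0 genes with limma (at most 199 at an unadjusted p under 0.05) against 4536, and at most 16 lists against 19, where again 1 split reached the real count. With 10 splits the share cannot be under 0.05. Every other split also held saline and YQSHJD libraries on both sides, so the difference between the groups widened the spread within each side. Few genes would pass there whatever the cause of that difference, so the count of 0 decides nothing.

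The change of a gene between the groups followed its GC content. A bias that differs between libraries could produce this: 5 of the 6 pairs of libraries within a group differed with GC content by more than 0.1 (Spearman). Of the 10 splits, 6, the real one included, gave a correlation as large as the real -0.453, with -0.628 as the largest of the others. Every other split held saline and YQSHJD libraries on both sides. A trend that came with the treatment could give such values too, so the splits cannot tell it from a bias between libraries. Bias as the cause of the fall of mitosis and replication genes is argued against, since 43 of the 43 members called lower stayed lower after GC correction. What stays open is how much of the GC trend came with the treatment.

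The rise of the mitochondrial rRNAs was larger than that of the mitochondrial mRNAs. GC bias is argued against, because the smaller of the 2 rRNA differences was still 1.558 after correction. More mitochondrial RNA of every kind is argued against by a median of 0.214 (SD 0.454) over the 13 mRNAs. Weaker poly(A) selection stays open: it would raise histone mRNAs by about as much as MT-RNR2, and the 6 tested ones had a median of 0.395 (SD 0.914), but 3 were higher and 0 lower, H1-2 at 2.41 rose more than MT-RNR2, and replication genes fell. A gradient along the heavy strand may contribute, since over 14 genes the difference fell with position at a Spearman rho of -0.587 (permutation p = 0.03), but without the rRNAs rho was -0.343 over 12 genes (permutation p = 0.28), so the relation rests on them. Genes are not independent replicates, and a change in rRNA processing or stability with treatment was not tested.

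ID1 fell together with SMAD6, SMAD7, SMAD9, BAMBI and ATOH8, further targets of BMP-SMAD signalling, at log2 differences of -0.96, -1.03, -1.11, -0.94 and -0.87. GC bias is argued against, since 6 of the 6 genes stayed lower after GC correction. All 6 stayed lower under each of the 3 scaling alternatives. All 3 move the median of all genes down, so that count alone decides nothing. A scaling, however, shifts the genes of a library about alike. The median of all tested genes was 0.038, and -0.29 under TPM rescaling, while the 6 genes lay between -0.87 and -3.98. These values argue against scaling as the cause of the fall of the 6 genes relative to other genes. On a second list of targets, 3 of 5 tested genes were lower (MSX1 at -0.57, JUNB at -0.79 and GATA6 at -0.91), while SMURF1 was higher at 0.31 (adjusted p = 0.0429) and SMURF2 stood at 0.35 (adjusted p = 0.0654). JUNB had been tested before in the list of immediate early genes, and without it 2 of 4 were lower, so whether BMP-SMAD signalling was lower with YQSHJD stays open.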
